A study of Arabidopsis thaliana with 10 samples.

How the data were processed

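Chromatin immunoprecipitation with an anti-GFP antibody was followed by sequencing in Arabidopsis seedlings that carried a YFP-tagged LIMYB transgene, per the labels. LIMYB is a MYB-domain protein of the NIK1 receptor kinase pathway. The 10 samples fell into 3 groups by the line given in their labels: L1 (2 samples), L3 (4 samples) and L4 (4 samples). Replicates carried the numbers 1 and 2, and in L3 and L4 each number occurred with 2 title suffixes. All titles also carry the name LIMYB-32, whose meaning the labels do not give, and whether L1, L3 and L4 are independent transgenic lines or derive from 1 line is not stated. Seedlings were crosslinked with formaldehyde, nuclei were isolated and TruSeq ChIP libraries were made, per the labels' protocols. No group of control immunoprecipitations or input DNA is among the samples.

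One annotated peak list per line was used, and no column names a sample. The lists therefore give no replicate error, and no test between the lines was possible. MACS2 is named in the submitters' processing notes; its version and settings, the aligner, the genome build, the control track and whether replicates were pooled are not given in the sources used here. The deposited pileup is the signal, in overlapping fragments, at a peak's summit as the authors' peak caller wrote it. The deposited fold enrichment is read here as a ratio of that signal to a local background. The file headers give its name but not its denominator. The deposited q-value is on a −log10 scale, per the file headers. These are the authors' own values per peak, and they were used to describe, rank or filter peaks within a list. Across lists they served in 3 places, none of which tests a difference between lines. The rule for named genes orders genes by the lower of their folds in L1 and L4. Folds of the 4319 shared peak pairs were correlated across peaks, which are not independent (Spearman's rho 0.477, Pearson's r 0.535, permutation p = 0.0001 for each, the smallest possible). Plastid pileups and backgrounds of the 3 lists are set side by side as values. Sequencing depth per sample is unknown.

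A peak assigned to several genes was counted once by its position: 9775 entries in L1 held 9759 peaks, 9160 in L4 held 9145, and 12 in L3 held 12. Each peak was assigned by the authors to a protein-coding transcript's gene by nearest location, per the file headers. In 98.9% of entries in L1 and 99.0% in L4, that gene had the 5′ end nearest to the peak start among the genes named in the lists. Distances here run from the summit to the 5′ end of the assigned gene. Symbols came from a RefSeq table of the TAIR10.1 assembly, from which no coordinates were taken; 9825 of 10143 assigned identifiers (96.9%) were in it. None of the organelle identifiers matched, so these are given as in the files. The table lists 27432 nuclear protein-coding genes, which were the background of the list tests. Positions are those of the files.

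Peak sharing between L1 and L4 meant an overlap of at least 1 bp on the 5 nuclear chromosomes. It was tested one-sided against 1000 random placements of the L4 peaks within their chromosomes. Chromosome shares were tested two-sided with 1000 random placements over all 5 chromosomes, with Benjamini-Hochberg adjustment over 10 tests. The length of a chromosome was taken as the largest peak end in L1 or L4. A gene counted as bound when a peak assigned to it overlapped the window from 1000 bp upstream to 100 bp downstream of its 5′ end. Bound shares of 15 gene lists were compared with those of all other genes by two-sided Fisher's exact tests in L1, L4 and both, with Benjamini-Hochberg adjustment over these 45 tests and a threshold of 0.05. Shares of peaks or genes have 95% Wilson intervals, which cover counting error only; neighbouring peaks and co-expressed genes are not independent. Family screens used symbol stems shared by at least 20 genes.

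The background behind a peak was derived as (pileup + 1) / fold − 1. This assumes a pseudocount of 1 in the peak caller, which no source used here records. Work was done with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Overlap and list tests were checked on simulated data. With 30% of L4 peaks planted on L1 peaks, 32.7% of the 8952 L4 peaks were recovered as shared, against 4.09% with none planted. For lists of 13 among 27432 genes, the unadjusted test called 94.5% of 200 lists with 40% planted, 67.5% with 25% and 3% with 4%.

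Groups, tests, 12 lists of loci, rules for 3 further lists and the rule for named genes were fixed before the data were examined. The series description says the study asks about translational machinery and photosynthetic genes, and lists for both were included for that reason. The rule for named genes was as follows. It takes all members of the NIK1-RPL10-LIMYB list, the 10 highest folds in L1 and in L4, and all L3 peaks. It also takes up to 5 bound members per list ranked by the lower fold of both lines, and up to 10 other genes bound in both. Alternatives were other overlap rules, stricter peak thresholds, a window of 2000 bp upstream to 200 bp downstream, the assigned gene at any distance, the gene body, genes bound in either line and covered length per chromosome. Chosen after seeing the data were L4 peaks moved by at most 50000 bp, peaks within 10000 bp of a gene, joined photosynthetic lists, a second ribosomal list of 50 genes with RPL or RPS symbols, and overlapping promoter peaks.

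Several planned steps changed. The window was applied only to the gene the authors assigned, since no strand was held for other genes. The placement test of summits near 5′ ends and the motif tests needed a genome and were not run. A tRNA list was not tested, since the lists assign only protein-coding genes, and organelle-encoded genes were only counted. Ribosomal proteins and translation factors were found by symbol or synonym, which covers part of these families: 48 cytosolic, 19 organellar and 26 factor genes.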

Results

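The data were peak lists of YFP-LIMYB chromatin from Arabidopsis seedlings of 3 lines, L1 (2 samples), L3 (4 samples) and L4 (4 samples). Whether these are independent transgenic lines is not stated in the labels, so peaks shared by L1 and L4 may not be shared by separate transgene insertions. The question was where on the genome LIMYB, a MYB-domain protein downstream of the receptor kinase NIK1, was found. L1 had 9759 peaks, L4 had 9145 and L3 had 12. On the nuclear chromosomes L1 had 9604 peaks and L4 had 8952, and L3 had none. Nuclear peaks were narrow, with a median width of 225 bp in L1 and 238 bp in L4. The median fold enrichment was 8.72 in L1 (quartiles 7.31 and 10.96) and 11.65 in L4 (quartiles 9.34 and 14.86). The median pileup was 19 fragments in L1 and 17 in L4, and the median −log10 q was 10.27 and 10.99. Because each line had a single list, no value per peak carries a replicate error.

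All 12 peaks of L3 lay on the plastid genome. The highest pileup, 57 fragments with a fold of 18.75, was upstream of ATCG00690 at plastid positions 73566 to 74008. The highest fold, 22.47 with a pileup of 40, was upstream of ATCG00430 at 49940 to 50170. The peak at 33207 to 33418 upstream of ATCG00280 had a fold of 12.26, and that at 81164 to 81403 upstream of ATCG00780 had 11.76. Peaks inside ATCG00120 and ATCG01010 had folds of 11.45 and 10.9. Those across the 3′ ends of ATCG00300, ATCG01040 and ATCG01310 had 14.23, 10.05 and 18. Those across the 5′ ends of ATCG00870, ATCG00905 and ATCG01230 had 15.83, 12.67 and 19.35. Each of the 12 overlapped a plastid peak in L1 and one in L4. L1 had 73 plastid and 82 mitochondrial peaks, assigned to 48 and 58 organelle-encoded genes. L4 had 93 and 100, assigned to 59 and 66.

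Nuclear peaks were spread over all 5 chromosomes and were densest in a few regions near the centromeres. In L1 the densest 500000-bp bin was chromosome 1, 15000001 to 15500000, with 94 peaks against a median of 38 over 235 bins. In L4 it was chromosome 2, 3000001 to 3500000, with 87 peaks against a median of 36. That chromosome 2 bin had 85 peaks in L1, and the chromosome 1 bin had 68 in L4. Whether reads from organelle DNA can map to these nuclear bins was not examined. In L1, 8 bins exceeded the highest count in 1000 random placements (71 peaks), and in L4, 2 bins did (68 peaks). Chromosome 1 held 24.3% of L1 peaks, where its length predicts 25.5%, and chromosome 2 held 17.5% of L4 peaks, where 16.5% is predicted. Both had an adjusted p of 0.05 in the two-sided permutation test. This value comes from rounded p-values and sits at the threshold, so neither share is called on either side of it. No other chromosome was below the threshold. By covered length, chromosome 1 held 24.1% in L1 and chromosome 2 held 17.6% in L4, each with a permutation adjusted p of 0.015.

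**Figure D1:**
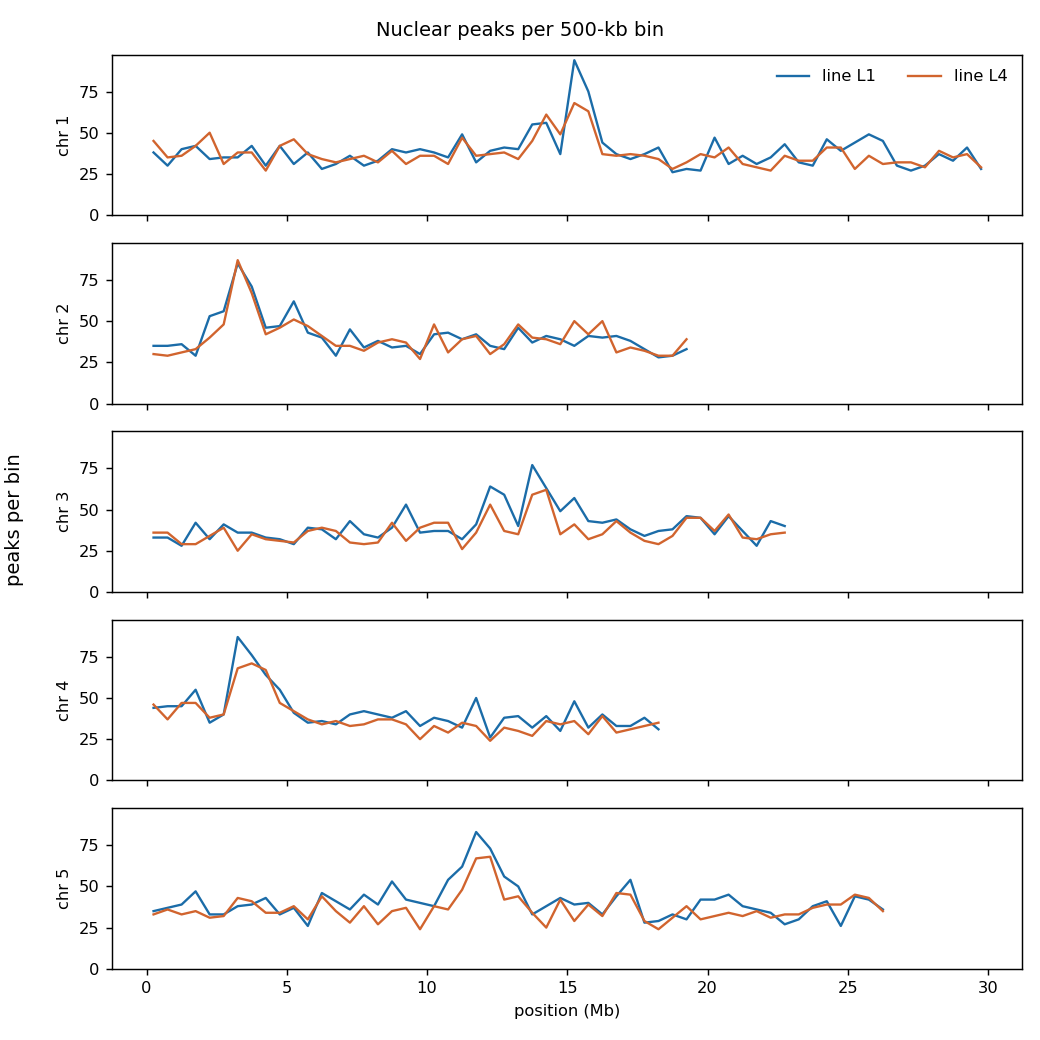
Nuclear peaks per 500000-bp bin (vertical axis, count) along each of the 5 chromosomes (horizontal axis, Mb), for L1 (blue) and L4 (orange). Both lines rise in the same regions, to 94 peaks in L1 on chromosome 1 and 87 in L4 on chromosome 2, from medians of 38 and 36.

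Most peaks lay outside the genes they were assigned to. In L1, 42.4% of nuclear peaks (95% interval 41.4 to 43.4) lay upstream, 26.0% (25.1 to 26.9) inside and 19.5% (18.7 to 20.3) downstream of the assigned gene. In L4 these shares were 40.5% (39.5 to 41.5), 27.8% (26.9 to 28.8) and 18.9% (18.1 to 19.8). Of all nuclear peaks, 12.0% in L1 and 11.3% in L4 lay upstream or downstream at more than 10000 bp from the assigned gene. Summits were frequent just upstream of 5′ ends: 1273 in L1 and 1196 in L4 lay within 500 bp upstream, and 692 and 631 within 500 bp downstream. This held only near the 5′ end. From 500 to 1000 bp, each 100-bp bin held more summits downstream than upstream in both lines. Between 800 and 900 bp there were 199 in L1 and 239 in L4 downstream, against 135 and 121 upstream. The promoter window of 1000 bp upstream to 100 bp downstream held 22.7% of L1 summits (21.9 to 23.6) and 22.4% of L4 summits (21.6 to 23.3). The windows of all 27432 nuclear genes would cover at most 25.4% of the chromosomes, but the shares count the window of the assigned gene alone, and no placement test was run, so neither an excess nor its absence was shown. Assignment to the nearest 5′ end also shapes the distances.

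**Figure D2:**
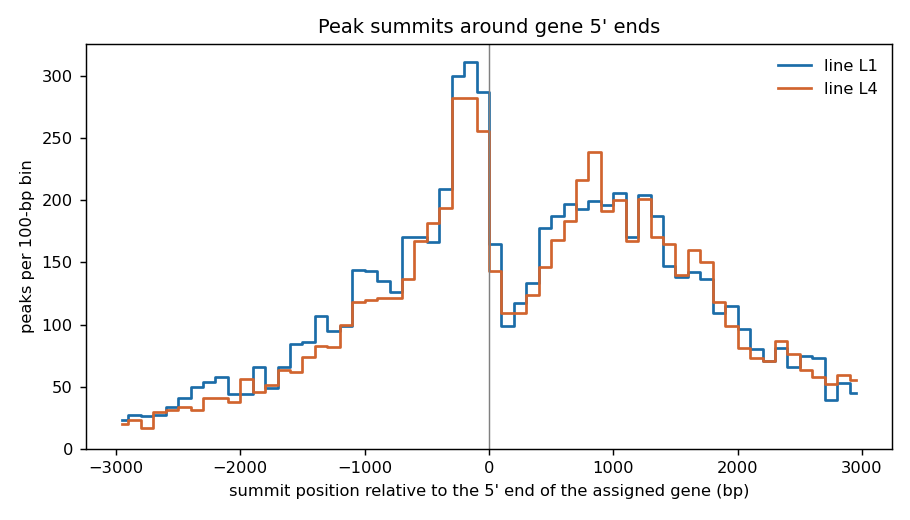
Peak summits per 100-bp bin (vertical axis, count) by distance from the 5′ end of the assigned gene (horizontal axis, bp, upstream negative), for L1 (blue) and L4 (orange). Counts are highest in the bins within 300 bp upstream, at up to 311 in L1 and 282 in L4, and lowest near the 5′ end from 100 to 200 bp downstream in L1 (99).

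L1 and L4 shared many of their nuclear sites, far more than random placement gave. Of 9604 L1 peaks, 4319 (45.0%) overlapped an L4 peak, and of 8952 L4 peaks, 4316 (48.2%) overlapped an L1 peak. Random placement gave a mean of 361.2 L1 peaks (304 to 418), so the observed number was 12.0 times higher (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Random placement holds no background common to both lines, and no control immunoprecipitation or input is among the samples. Sites drawn by such a background would also exceed it, so the excess does not by itself show LIMYB binding. Summits of shared pairs lay a median of 23 bp apart. In the 10% of peaks with the highest folds, 83.5% of L1 peaks (81.1 to 85.8) and 70.4% of L4 peaks (67.3 to 73.3) were shared. The share did not rise evenly: in L1 it was 38.5% in the 10% with the lowest folds and 28.9% in the 4th of the 10 groups by fold. Of the L1 peaks in these groups, 31.4% and 7.08% lay more than 10000 bp from the assigned gene. Whether this accounts for the uneven rise was not tested.

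**Figure D3:**
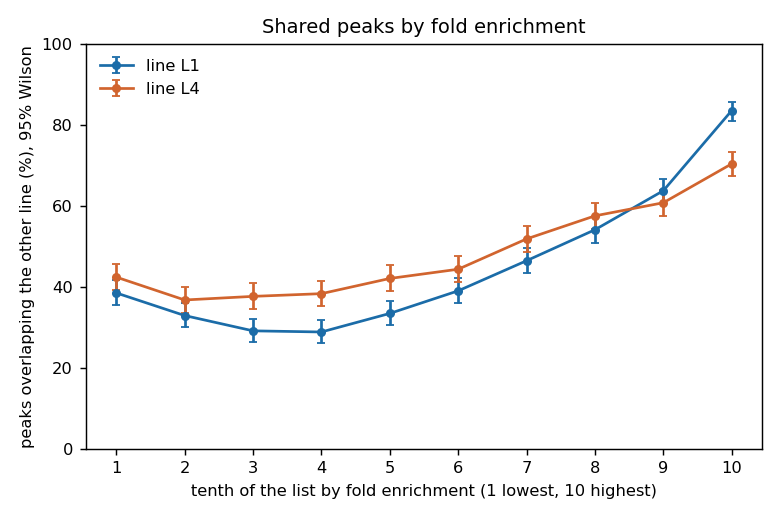
Share of nuclear peaks overlapping a peak of the other line (vertical axis, %) in 10 equal groups ranked by fold enrichment (horizontal axis, 1 lowest), for L1 (blue) and L4 (orange); bars are 95% Wilson intervals. The share reaches 83.5% in L1 and 70.4% in L4 in the highest group.

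Most of the sites with the highest folds were common to both lines, with the same limit that no control was among the samples. All 10 L1 peaks with the highest folds overlapped L4 peaks, and 8 of the 10 highest in L4 overlapped L1 peaks. A site across the 3′ end of AT1G74730 on chromosome 1 had a fold of 32.48 in L1 and 41.6 in L4. A site inside PERK8 (AT5G38560), a proline-rich receptor-like kinase gene on chromosome 5, had 32.29 and 39.76. The highest fold of L1, 36.21, was downstream of AT5G37890. It was followed by sites assigned to AT5G03880 (35.71), AT2G45630 (35.37), AT5G67640 (33.94), the cyclin gene CYCD4;1 (32.54), ASL9 (32.3), NMD3 (32.12) and AT3G28850 (31.25). In L4, sites at AT4G21700 (41.36), AT5G41830 (41.35), AT4G16380 (40.91), AT5G28500 (40.09), AT1G62370 (39.34) and AT3G30370 (38.66) overlapped L1 peaks. The L4 sites inside AT1G22000 (39.33) and HL (AT5G54390, 39.15) did not. None of these 20 peaks touched the promoter window of its assigned gene.

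Genes with a promoter peak numbered 2378 in L1 (8.67% of 27432) and 2207 in L4 (8.05%). Both lines shared 1050 of these genes, 5.49 times the 191.3 of independent lists, and in 1016 the peaks themselves overlapped. Outside the lists, the genes ranked highest in both lines included LSM8, an RNA-binding protein gene, with folds of 27.52 in L1 and 28.32 in L4. PHO2, a regulator of phosphate homeostasis, had 26.47 and 29.58, with summits 30 and 7 bp downstream of its 5′ end. The sucrose transporter gene SWEET11 had 24.54 and 30.36, and TRP1, of tryptophan synthesis, had 23.2 and 26.89. ATRER1C1 had 23.49 and 31.72. AT5G01080, AT2G37120, AT5G47250, AT2G11773 and AT1G49940 were the other 5, with folds from 23.04 to 27.58 in L1 and from 28.03 to 35.49 in L4.

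Genes of photosynthetic electron transport and the plastid ATP synthase carried promoter peaks in both lines more often than other genes. Of 13 members, 5 were bound in both (38.5%, 95% interval 17.7 to 64.5) against 3.81% of other genes (odds ratio 15.8, Fisher's exact adjusted p = 0.00365). In L4, 6 of 13 were bound (46.2% against 8.03%, odds ratio 9.82, Fisher's exact adjusted p = 0.00633). In L1, 5 of 13 were bound (38.5% against 8.65%), which did not pass (odds ratio 6.60, Fisher's exact adjusted p = 0.0520). FED A (AT1G60950), a leaf ferredoxin gene, had peaks at chromosome 1, 22444159 to 22444400 in L1 (fold 16.28) and 22444110 to 22444405 in L4 (fold 28.47). PDE334 (AT4G32260), for a plastid ATP synthase subunit, had folds of 14.23 and 34.78, with summits 85 and 76 bp downstream of the 5′ end on chromosome 4. FD1, another ferredoxin gene, had 10.96 and 16.25. FNR1, for ferredoxin-NADP reductase, had 13.91 and 9.6, and PETE1, for plastocyanin, had 8.35 and 21.83. In these 5 genes the peaks of L1 and L4 overlapped. A close gene copy exists for 4 of them, all but PDE334, and for 9 of the 13 members. Whether the copies share reads at these peaks was not examined. The L4 call was lost when the gene body replaced the promoter window (odds ratio 4.39, Fisher's exact adjusted p = 0.0944). The L1 list passed with the assigned gene at any distance (Fisher's exact adjusted p = 0.00911) and in the upper 50% of peaks by fold (0.0384).

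The antenna and photosystem lists had raised shares of promoter peaks that did not pass adjustment. Of 21 light-harvesting antenna genes, 6 were bound in L1, 6 in L4 and 4 in both (19.0%, odds ratio 5.93, Fisher's exact adjusted p = 0.0569 in each set). LHCB5 had folds of 14.62 in L1 and 9.72 in L4, LHCA3 had 8.7 and 12.14, LHCB4.3 had 9.4 and 11.54, and CAB2 had 6.13 and 6.44. The LHCB4.3 peaks did not overlap each other, and CAB2 has near-identical neighbours that can share its reads. LHCB2.2 was bound in L4 (18.75). Of 12 photosystem I genes, 3 were bound in both (adjusted p = 0.0610, Fisher's exact test): PSAD-2 (6.79 and 22.57), PSAL (6.79 and 9.34) and PSAN (6.79 and 13.82). PSAG was bound in L4 (8.59). Of 15 photosystem II genes, 3 were bound in both (adjusted p = 0.0901, Fisher's exact test): PSBP-2 (16.19 and 24.62), AT1G51400 (8.35 and 20.24) and PSBP-1 (6.73 and 14.79). PSBW was bound in L1 (7.31). Antenna genes passed in L4 with the gene body (11 of 21, odds ratio 7.73, Fisher's exact adjusted p = 0.000538) or at any distance (odds ratio 6.20, adjusted p = 0.00115), and in both lines with either definition (6.33 and 5.45) and when bound in either line (4.17). In no set did antenna genes pass with 2000 bp upstream to 200 bp downstream, or in the upper 50% of peaks by fold. Nor did they pass with overlapping promoter peaks (odds ratio 4.34, Fisher's exact adjusted p = 0.184). Whether near-identical antenna genes share reads within gene bodies was not examined. In the upper 50% of peaks by fold, 0 photosystem I genes were bound in L1 or in both lines.

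**Figure D4:**
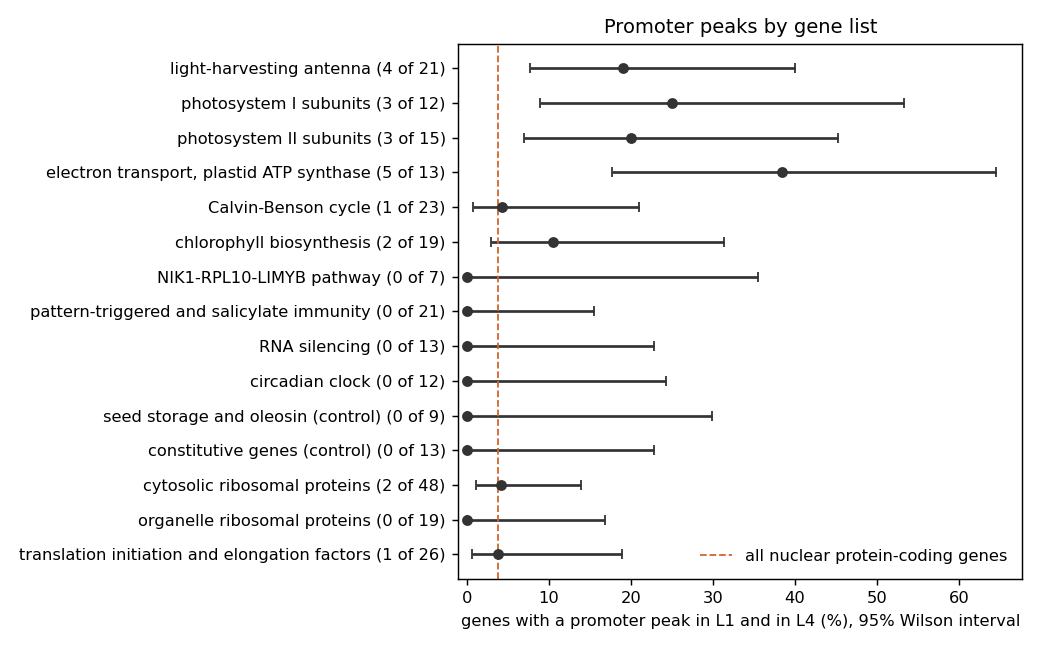
Share of each gene list with a promoter peak in L1 and in L4 (horizontal axis, %), with 95% Wilson intervals and bound members of all members in brackets; the dashed line is the share of all nuclear protein-coding genes. The electron transport and plastid ATP synthase list, at 5 of 13, is the one list that passed adjustment in this set.

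Promoter peaks at carbon fixation and pigment genes did not pass in any set. Of 23 Calvin-Benson cycle genes, 2 were bound in L1, 4 in L4 and 1 in both (odds ratio 1.14). In L4 the odds ratio was 2.41, and the list passed with the gene body (9 of 23, odds ratio 4.52, Fisher's exact adjusted p = 0.0129) or the assigned gene at any distance (13 of 23, odds ratio 4.03, adjusted p = 0.00881). The gene bound in both was GAPA, for a plastid glyceraldehyde phosphate dehydrogenase subunit (8.91 and 8.59). RBCS3B (12.05), HCEF1 (10.14) and GAPA-2 (10.12) were bound in L4, and SBPASE (9.4) in L1. Of 19 chlorophyll synthesis genes, 3 were bound in L1, 4 in L4 and 2 in both (odds ratio 2.96, Fisher's exact adjusted p = 0.490). G4, the chlorophyll synthase gene, had folds of 19.09 and 25.89, and PORB had 9.26 and 12.05. CRD1 (15.57) and CHLM (12.45) were bound in L4 and GSA2 (9.4) in L1.

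Promoter peaks at ribosomal protein and translation factor genes did not pass in any set, and these lists' odds ratios lay on both sides of 1 across the alternatives. Of the 48 cytosolic ribosomal protein genes found by symbol or synonym, 3 were bound in L1, 6 in L4 and 2 in both (4.17%, 95% interval 1.15 to 14.0, against 3.83%). The 2 were RPS5B (9.13 and 14.19) and RPL12-C, with folds of 8.88 in L1 and 8.45 and 17.12 at a pair of L4 peaks. RPL12-A (14.79), RPL5B (11.68) and PFL (9.7) were bound in L4. RPL12-A and RPL12-C encode plastid proteins that the symbol rule left in this list. Of 19 organellar ribosomal protein genes 1 was bound, MRPL11 in L1 (9.4). Of 26 translation factor genes, 4 were bound in L1, 1 in L4 and 1 in both, EIF2 (AT2G39990, 7.83 and 10.9). The EIF2 peaks of L1 and L4 did not overlap each other. EIF3G1 (9.92), EIF2 GAMMA (9.4) and EIF4G (6.57) were bound in L1.

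No gene of the NIK1-RPL10-LIMYB list had a promoter peak. NIK1, NIK2, NIK3 and SAC52, an RPL10 gene, had no peak assigned. RPL10B had an L1 peak across its 3′ end (8.35), and SAG24, another RPL10 gene, had one inside (8.5). The LIMYB gene itself, AT5G05800, had a peak inside the gene in each line: chromosome 5, 1744054 to 1744365 in L1 (fold 6.15) and 1743616 to 1744289 in L4 (fold 13.31). The transgene holds the same coding sequence, and these peaks cannot be assigned to one copy or the other. With 0 of 7 promoters bound, the 95% interval reached 35.4%; with the gene body 3 of 7 were bound in L1 (odds ratio 5.22, Fisher's exact adjusted p = 0.192).

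Immunity, silencing, clock and control lists did not pass in any set, and their odds ratios lay on both sides of 1 across the alternatives. Of 21 genes of pattern-triggered and salicylate immunity, 0 were bound in either line (interval up to 15.5%; Fisher's exact adjusted p = 0.660 in L1 and 0.874 in L4). Of 13 RNA silencing genes, DCL3 was bound in L1 (5.74) and AGO4 in L4 (22.13). Of 12 clock genes, GI was bound in L1 (7.83) and CCA1 in L4 (7.78). Among the control lists, 1 of 9 seed storage and oleosin genes was bound, CRU2 in L4 (22.05). Of 13 constitutive genes, GAPC2 was bound in L1 (7.43) and UBQ11 in L4 (19.62). None of these lists had a member bound in both lines.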

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

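Peaks on organelle DNA stand outside the nuclear comparisons and were set apart for that reason; the tests below were chosen after their results were seen. L1 held 73 plastid and 82 mitochondrial peaks, and L4 held 93 and 100. No control samples gave a level to set these against. Of these, 67 plastid and 64 mitochondrial peaks of L1 overlapped peaks of L4.

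LIMYB was immunoprecipitated from nuclei, yet plastid peaks were the only peaks of L3. Within L1 the background derived from pileup and fold was 47.3 times higher on plastid than on nuclear peaks (medians). Within L4 it was 209 times higher. These ratios go with a high copy number of plastid DNA in the chromatin of L1 and L4, and they rest on the assumed pseudocount. L3 had no nuclear peak, so no such ratio exists for it. The median plastid fold was 13.45 in L3, against 3.14 in L1 and 2.73 in L4. Shallow L3 coverage may leave only the most abundant DNA above the calling threshold: the median plastid pileup was 27 in L3, 166 in L1 and 255 in L4, with median backgrounds of 1.01, 52.3 and 92.8, but whether the lists share a scale is not given. The L3 sites lay at a median of the 90.4th percentile of plastid pileups in L1 and the 90.9th in L4, and at the 85.6th and 84.4th percentiles of plastid folds, so abundant DNA and enriched sites cannot be told apart there. LIMYB binding to plastid DNA was not excluded, and no biological explanation was tested.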

How the results depend on the processing

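No paired analysis was possible because each line has a single peak list with no replicate columns; for the same reason no replicate was left out. Motif alternatives were not run. Moved L4 peaks, peaks near genes, joined lists, overlapping promoter peaks and a second ribosomal list were chosen after seeing the data. That list, 50 genes with RPL or RPS symbols, did not pass either (odds ratio 0.916 in L1, 1.86 in L4 and 1.61 in both; smallest Fisher's exact p = 0.119, unadjusted). Of 251 alternative values, 190 kept their direction and side of the threshold or stayed in range. L1 peaks sharing a site with L4 ranged from 40.3% to 45.6% over 6 alternatives, each with permutation p = 0.001. The electron transport list kept passing in the 6 alternatives set beside its result in both lines. Odds ratios were 9.88 to 16.7 for genes bound in both lines and 5.80 for genes bound in either line.

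At a −log10 q of at least 10, L1 kept 5207 peaks and L4 kept 5199. The upper 50% by fold held 4879, 4572 and, in L3, 6, by construction. By covered length, L1 chromosome 1 (24.1%) and L4 chromosome 2 (17.6%) passed, both at a permutation adjusted p = 0.015. Both count as changed, although their shares of peaks sat at the threshold, with a permutation adjusted p of 0.05 from rounded values. With 2000 bp upstream to 200 bp downstream, the share of summits in the window was 32.5% in L1 and 31.8% in L4, since the window is wider; in the upper 50% it was 24.3% in L1. Values below are odds ratios, and the cause of each change was not tested.

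With the assigned gene at any distance, antenna genes passed in L4 (6.20) and both (5.45), electron transport in L1 (6.52) and Calvin-Benson genes in L4 (4.03). With the gene body, antenna genes passed in L4 (7.73) and both (6.33), Calvin-Benson genes passed in L4 (4.52), and electron transport in L4 no longer did (4.39). Antenna genes bound in either line passed (4.17), and electron transport in L1 passed in the upper 50% (8.94).

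Another 41 odds ratios, none passing in either setting, crossed 1. With the gene body these were chlorophyll synthesis in L1 (0.819), the NIK1-RPL10-LIMYB list (5.22 in L1, 1.17 in L4, 2.63 in both), immunity (1.16, 1.17 and 1.66), RNA silencing (1.27, 1.27 and 1.31), seed storage in L4 (0.876), constitutive genes (1.27 in L1 and 1.27 in L4), cytosolic ribosomal proteins in L1 (1.19) and translation factors in both (0.630). With the assigned gene they were NIK1-RPL10-LIMYB in L1 (2.17), seed storage in L4 (0.387), constitutive genes in L1 (2.48) and both (1.80), cytosolic ribosomal proteins in L4 (0.814) and both (0.544), and translation factors in L1 (0.868) and both (0.780). In the upper 50% they were photosystem I in L1 and both (0), Calvin-Benson in both (0), RNA silencing in L4 (1.84), clock in L4 (0), constitutive genes in L4 (1.84), cytosolic ribosomal proteins in L1 (1.34), organellar ones in L1 (1.12) and translation factors in both (0). In the wider window they were Calvin-Benson in L1 (0.736) and both (0.843), clock in L4 (0.780), constitutive genes in L1 (3.44) and cytosolic ribosomal proteins in both (0.806). Bound in either line, they were RNA silencing (1.23), clock (1.35) and constitutive genes (1.23), and with overlapping promoter peaks, translation factors (0). Most of these lists have under 25 genes, so 1 bound gene can move a value across 1.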

Other observations

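All tests in this part were chosen after the results they bear on were seen. Joined into one list, the 61 antenna, photosystem and electron transport genes had 15 members bound in both lines (24.6%, 95% interval 15.5 to 36.7) against 3.78% of other genes (Fisher's exact odds ratio 8.30, p = 6.8e-09). The joined lists had each been seen to lean upward, so this p is not independent evidence. In 14 of the 15 genes the L1 and L4 peaks overlapped each other. Of 62 gene families by symbol stem, 186 tests gave none with an adjusted p below 0.05; 7 were below 0.05 unadjusted, where the CPK kinases in L4 had the smallest p (8 of 29 bound, odds ratio 4.37, Fisher's exact p = 0.00160, adjusted p = 0.298).

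Reads shared between close gene copies may account for part of the photosynthetic promoter peaks. Of 27 photosynthetic genes with a single gene per subunit, 5 were bound in both lines (18.5% against 3.81% of other genes). The odds ratio was 5.73 (Fisher's exact p = 0.00325). These genes come from the lists joined for leaning upward, so this p is not independent evidence. No sequences were compared, so shared reads were not excluded for these genes. Of 34 with a close copy, 10 were bound (29.4%, odds ratio 10.6). The 2 shares did not differ past the threshold (Fisher's exact p = 0.382), so shared reads stay open. In the electron transport list, 4 of 9 genes with a close copy were bound in both lines, and 1 of 4 without. These counts are too small to decide the question. Strong transcription may also draw an antibody to open promoters: 2 of 61 ribosomal protein and constitutive genes were bound in both lines, below the photosynthetic share (Fisher's exact p = 0.00111), but no expression values or control immunoprecipitation were used here, so this stays open too. No biological explanation was tested, since the design holds no group without the tagged protein.

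The peak inside the LIMYB gene may come from the transgene's own LIMYB sequence. Across both lines 0 of its 2 peaks overlapped the gene's promoter window, which decides nothing, since most peaks of both lists lie outside such windows. The L4 peak, 674 bp wide, was among the widest 0.346% of its list, while the L1 peak, 312 bp wide, was among the widest 11.6%. Binding within the gene and transgene fragments cannot be told apart without reads.

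The 20 nuclear peaks of highest pileup in L1 all overlapped L4 peaks, and 9 lay more than 10000 bp from the assigned gene. Of the 20 in L4, 19 overlapped L1 peaks and 8 lay that far. Their median fold was 3.785 in L1 and 4.51 in L4, below the 8.72 and 11.65 of all nuclear peaks. With no control among the samples, this sharing does not by itself show LIMYB binding. The highest pileup in both lines was on chromosome 3, at 13589958 to 13592577 in L1 (fold 3.84) and 13591036 to 13592497 in L4 (fold 4.82).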
